A study of Mus musculus with 40 samples.

How the data were processed

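The labels describe mouse lung organoids, embryonic lung tips and organoid pieces. According to them, total RNA was extracted with TRIzol, libraries were made with the VAHTS mRNA-seq v2 kit and sequenced on an Illumina NovaSeq X Plus. The authors deposited 5 tables of TPM values per gene, made with RSEM and Bowtie2 on the mouse genome mm10 per the labels, which give no versions. Reads and counts were not used here. TPM keeps no sequencing depth, so depth per sample and the counting precision it would give are unknown. Column totals were 997840 to 999209 TPM.

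Of the columns, 40 were matched to samples by title and 1 column without a sample was left out. Of these libraries, 8 form the numbered groups ALL, ALL-FGF10, ALL-MTG and ALL-VC (2 replicates each). The tips and organoids give 14, pieces and the intact organoid 9, LO 4 and 2C 5, including 1 ALL library without a replicate number, which stands in another table than the numbered ones. The abbreviations F10, MTG, VC, 2C, DCI, LO and ALL are not defined in the labels and were used as names. The labels do not say whether replicates came from separate animals or cultures. No 2 libraries were identical. Within tables, Pearson correlations between libraries on log2(TPM + 1) ran from 0.905 to 0.980 for the culture groups and from 0.929 to 0.960 for the pieces. They ran from 0.953 to 0.969 between tips, from 0.921 to 0.959 between organoids and from 0.769 to 0.862 between a tip and an organoid.

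The 4 tables other than LO list 55260 gene symbols, all matched to GENCODE M21 annotation on GRCm38, from which coordinates and transcript lengths were taken. The LO table lists 55286, of which 26 are found only there and 11 have names turned into dates, as a spreadsheet does. Genes were kept in a fit with TPM of at least 1 in at least 2 libraries. Values were taken as log2 with a pseudocount of 1 TPM. Analyses used R 4.3.3 with limma 3.58.1, and figures Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6.

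Differences were tested with limma (lmFit, then eBayes with a trend of variance on mean), two-sided, with Benjamini-Hochberg adjustment over the genes of a contrast. A gene is called at adjusted p under 0.05. The 8 numbered libraries shared 1 fit without covariates, from which the 3 omissions against ALL and the 3 contrasts between omissions were taken. Organoids and tips were compared as 2 groups. A second fit on the same 14 libraries gave a slope on culture day and on start stage in organoids and on embryonic day in tips, multiplied by the ranges of 21, 4.5 and 3 days. Pieces were fitted with terms for up or down, left or right, piece size and the intact organoid. For slopes and pieces, replicates are lacking at most settings, and the spread around the fitted lines stands in for it. Where each group had 1 library, genes were counted when log2(TPM + 1) differed by at least 1 with TPM of at least 5 in the higher library, without a p-value.

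Before the data were examined, the groups, the tests other than fry, the gene lists and most alternative settings were fixed. The 28 lists hold 416 genes from textbook knowledge of lung cell types, of other cells that tips may carry, of signalling targets and of stress, 1 of which is absent from the tables. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a contrast. The fry test was not part of the plan fixed beforehand. Members were also counted with adjustment over the list alone. For single libraries, a list's median was set beside 10000 random lists of the same size and matched abundance. Lists of imprinted, MHC class II, ribosomal RNA-like, mitochondrial tRNA synthetase, ribosomal protein copy and sex-linked genes were drawn up after the values were seen.

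Genes were named by a rule fixed in advance: the 8 largest rises and 8 largest falls among called genes with TPM of at least 5 in the higher group, without predicted, clone or mitochondrial genes, plus up to 4 called members per list. For the culture groups the libraries of the 2 groups also had to be without overlap. The rule gave 988 gene and contrast combinations. Of the 209 combinations considered for the text, 12 lie outside it and were chosen after their values were seen. Genes shared by several omissions were named for being shared.

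The test was tried on simulated libraries that held known changes. Changed genes were drawn only from those with a mean log2(TPM + 1) above that of 5 TPM. The shares below therefore do not cover tested genes of lower abundance. For ALL-FGF10 against ALL the simulation covered 14137 genes, where the real fit covered 14802, so the shares may not hold for every gene. Of genes changed by a log2 of 1, 29.9% were called for ALL-FGF10 against ALL, 20.9% for ALL-MTG against ALL-VC, 80.6% for organoids against tips and 10.4% for pieces against the intact organoid. At a log2 of 2 the shares were 89.6, 64.2, 91.0 and 61.2%, and at 3 they were 92.4, 92.4, 98.5 and 78.8%. Absence of a call for a change near 2-fold is therefore weak evidence in the small groups.

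Alternative settings chosen in advance were a pseudocount of 0.1, other filters, median-ratio rescaling, quantile normalization, eBayes without trend or with robust estimation, fewer libraries, a replicate block, and each library left out in turn. After the values were seen, a term for the listing of genes of 100 to 150 nt, fits on libraries of 1 such kind, genes of at least 300 nt, the organoids alone and the unnumbered ALL library against 2C were added. No gene of 100 to 150 nt was above 0 TPM in 18 libraries, and 21 to 171 were in the other 22. What made this difference is not stated in the labels.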

Results

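The series held transcript abundance for mouse branching lung organoids and for the embryonic lung tips from which such cultures start, in TPM, the share of all transcripts scaled to a fixed total. Of the 40 libraries, 8 formed 4 culture groups with n = 2 each: ALL, read here as a complete condition, and ALL-FGF10, ALL-MTG and ALL-VC, read as omissions. The labels do not define ALL. Reading it as complete, a minus sign as an omission and a plus sign as an addition is an assumption. A further 14 covered tips at E10.5, E11.5, E12.5 and E13.5 (n = 4, 1 per stage) and organoids grown from E9.5 to E14 tips for 11 to 32 days (n = 10, 1 per combination). The other 18 were 1 intact organoid with 8 cut pieces, 4 libraries labelled LO and 5 of a set labelled 2C, each n = 1. Sequencing depth was unknown because TPM keeps no depth. Each library listed 13036 to 14418 genes at 1 TPM or more, with 6.54 to 15.2% of TPM from mitochondrial genes. Changes are differences of log2(TPM + 1), a scale that understates changes in genes of low abundance. The p-values measure only the spread between these samples.

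The first question was which genes differed between ALL-FGF10 and ALL, read as FGF10 left out of the complete condition. Cfb, encoding complement factor B (chromosome 17, 34856374 to 34862518), fell from 100.3 ± 26.2 to 6.01 ± 3.82 TPM (n = 2 each, log2 change -3.95 ± 0.64 SE, adjusted p = 0.034). Pigr, the receptor that carries IgA across epithelium (chromosome 1, 130826684 to 130852249), fell from 97.9 ± 6.99 to 6.29 ± 2.55 TPM (-3.81, adjusted p = 0.034). The tight junction gene Cldn4 (chromosome 5, 134945119 to 134946934) fell from 60.1 ± 22.2 to 11.2 ± 1.67 TPM (-2.28, adjusted p = 0.0089). By limma, 271 of 14802 genes differed at Benjamini-Hochberg adjusted p under 0.05, 130 higher and 141 lower. Among the lower genes were Cd177, a neutrophil surface antigen (-4.11), the peroxidasin gene Pxdn (-3.53) and the interferon-inducible nuclear body gene Sp100 (-3.27). The mitochondrial leucyl-tRNA synthetase gene Lars2 fell by 3.24, the kinase gene Sgk1 by 2.15 (24.4 ± 6.11 to 4.68 ± 0.976 TPM), the YAP target Ccn1 by 1.70, the stress gene Trib3 by 1.49 and the keratin gene Krt19 by 1.05. Among the higher genes were Hc, encoding complement C5 (164 ± 39.5 to 507 ± 46.4 TPM, log2 change 1.64, adjusted p = 0.022), and Glb1l, a galactosidase relative (2.70). The zinc finger gene Zfp993 was also called (4.68). Rps12l1, a processed copy of a ribosomal protein gene, was listed at 447 and 637 TPM in ALL-FGF10 and at 0 in the other 6 libraries, and Snhg9 at 20.3 and 10.1 TPM against 0 in both ALL libraries. The ALL library without a replicate number, in another table, held Zfp993 at 43.3, Rps12l1 at 131 and Snhg9 at 19.3 TPM, and reads of Rps12l1 and of its parent Rps12 are hard to separate, so these 3 calls are uncertain and may not follow from FGF10. That library also held Cfb and Pigr at 0, Cd177 at 0.06, Sp100 at 0.87, Pxdn at 2.23, Lars2 at 56.7 and Hc at 382 TPM. The falls of Cfb, Pigr, Cd177, Sp100, Pxdn and Lars2 may therefore reflect high values in the numbered ALL libraries. Likewise, the rise of Hc may reflect low values there. In the unnumbered library Sgk1, at 34.7 TPM, was not below the numbered ALL mean of 24.4. Its Cldn4 was near that of the numbered ALL libraries.

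Of the preset gene lists, few members were called without FGF10. AT2 (surfactant-making alveolar type 2) markers had 1 of 20 higher over all genes, and 1 adjusted over the list alone. AT1 (flat alveolar type 1) markers had 0 of 20, then 3 higher and 2 lower adjusted over the list alone. FGF response genes had 0 of 14, then 2 lower adjusted over the list alone. General lung epithelium genes had 2 of 18 lower, then 2 higher and 8 lower. Interferon genes had 0 of 14, then 2 lower, with a median of -1.48. The ALL library without a replicate number held Isg15 at 0.54, Ifit1 at 0.40 and Oasl2 at 0.58 TPM, but Ifit3 at 27.4. That median may therefore partly reflect high values in the numbered ALL libraries. For the interferon list, camera with a preset correlation of 0.01 gave adjusted p = 0.0011 (adjusted p = 0.86 with an estimated correlation). The fry test, which asks whether the genes of a set move, on balance, one way, gave adjusted p = 0.63. The count was 9 without ALL-FGF10 replicate 2, 11 without its replicate 1, 123 and 125 without ALL-VC replicates 2 and 1, 145 without ALL replicate 2 and 1149 without ALL replicate 1 (76.3% of them higher, against 48.0%). Genes of 100 to 150 nt were listed above 0 TPM in both ALL-FGF10 libraries (54 and 119 genes) and in neither ALL library. With that difference as a term 68 genes were called, 32 of the 271 among them.

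Leaving out MTG was compared with ALL in the same fit. Chil1, a chitinase-like gene of AT2 cells (chromosome 1, 134182176 to 134190181), fell from 1704 ± 1288 to 25.8 ± 23.3 TPM (n = 2 each, log2 change -6.09 ± 0.72 SE, adjusted p = 0.026). The kininogen gene Kng2 (chromosome 16, 22985854 to 23029482) fell from 57.8 ± 3.54 to 1.81 ± 1.04 TPM (-4.44, adjusted p = 0.0018). In contrast to the FGF10 omission, Cldn4 rose, from 60.1 ± 22.2 to 248 ± 43.4 TPM (2.07, adjusted p = 0.032). In all, 76 genes were called, 20 higher and 56 lower. The lower set held complement genes C3 (-3.96) and Cfb (-5.14), the chemokine gene Cxcl3 (-3.83), Pigr (-4.39), Cd177 (-5.14), Lars2 (-3.88) and the lysozyme gene Lyz2 (-3.54). The higher set held the activin antagonist gene Fst (3.08), the calcium channel gene Cacna1a (2.58), the matrix genes Col18a1 (1.65) and Lama3 (48.6 ± 6.77 to 124 ± 5.07 TPM, 1.34), the calcineurin regulator gene Rcan1 (1.51) and the growth factor gene Tgfb2 (16.0 ± 1.95 to 46.6 ± 1.48 TPM, 1.49). The ALL library without a replicate number held C3 at 5.64, Cxcl3 at 1.35, Cfb and Pigr at 0 and Cd177 at 0.06 TPM, so those falls are uncertain. Its Chil1, at 98.23 TPM, was also below the ALL mean of 1704, and its Kng2, at 9.78 TPM, below the ALL mean of 57.8. It held Lyz2 at 7.05 TPM. Part of the falls of Chil1, Kng2 and Lyz2 may thus reflect high values in the numbered ALL libraries. In the unnumbered library Lars2 was 56.7 TPM. Its Cldn4 was near that of the numbered ALL libraries.

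In this comparison the AT2 list had 2 of 20 lower, and 9 lower adjusted over the list alone (median -0.81, camera adjusted p = 7.5e-09, adjusted p = 0.55 with an estimated correlation). WNT response genes had 0 of 12 called, and 9 higher adjusted over the list alone (median 1.06, camera adjusted p = 1.3e-04, adjusted p = 0.55 with an estimated correlation). The interferon list had 0 of 14, then 12 lower adjusted over the list alone (median -2.37, camera adjusted p = 8.5e-12, adjusted p = 0.55 with an estimated correlation). The unnumbered ALL library held Isg15 at 0.54, Ifit1 at 0.40 and Oasl2 at 0.58 TPM, but Ifit3 at 27.4. The interferon falls may therefore partly reflect high values in the numbered ALL libraries. Mesenchymal markers had 0 of 5 called by either count (median 1.35, camera adjusted p = 0.055), with Dcn at 168 and 6.57 TPM in ALL-MTG and 7.24 and 3.65 in ALL. Distal tip genes had 0 of 12, then 5 higher. Goblet markers had 0 of 5, then 1 lower (camera adjusted p = 0.046, adjusted p = 0.55 with an estimated correlation). Of these lists fry called none, with adjusted p = 0.077 for both AT2 and WNT response. Most of the 76 genes were no longer called when either ALL replicate was left out. Without ALL replicate 1, about as many called genes were higher as lower. The count was 18 and 20 without ALL-FGF10 replicates 1 and 2, 26 without either ALL-VC replicate 1 or replicate 2, 29 without ALL-MTG replicate 1, 191 without ALL-MTG replicate 2, 24 with the listing of 100 to 150 nt genes as a term (12 of the 76 genes among them), 11 with only the 2 groups compared (8 of the 76) and 7 without a filter on TPM (5 of the 76). The ALL-MTG libraries differed in sex-linked genes (Xist 291 and 0.31 TPM, Eif2s3y 0.13 and 79.6), as did the ALL libraries (Xist 6.04 and 147, Eif2s3y 74.5 and 0.22), and the 21 genes of 100 to 150 nt above 0 TPM in ALL-MTG replicate 1 were all at 0 in replicate 2.

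The omission of VC was the third comparison with ALL. The lysosomal protease gene Ctsz (chromosome 2, 174427493 to 174439039) fell from 107 ± 23.2 to 2.96 ± 2.40 TPM (n = 2 each, log2 change -4.91 ± 0.40 SE, adjusted p = 0.0065). Muc1, a membrane mucin gene (chromosome 3, 89229057 to 89233381), fell from 522 ± 186 to 57.1 ± 18.1 TPM (-3.16, adjusted p = 0.020). The growth factor gene Igf2 (chromosome 7, 142650766 to 142666816) rose, from 9.25 and 0.98 TPM in the ALL libraries to 120 and 84.5 (4.50, adjusted p = 0.041). Of 119 called genes, 31 were higher and 88 lower. The lower set held the MHC class II genes H2-Aa (-4.37) and H2-Ab1 (-4.80), the AT1 membrane gene Pdpn (21.3 ± 1.62 to 0.725 ± 0.0919 TPM, -3.69), the inflammasome adaptor gene Pycard (-3.61), the ubiquitin ligase gene Rnf186 (-3.99), Pigr (-3.82) and the immunoproteasome gene Psmb8 (-1.92). The higher set held the adhesion gene Ceacam2 (3.92), the imprinted Notch ligand relative Dlk1 (3.59), the desmosome gene Perp (2.47), the transcription factor gene Gata4 (2.44) and Krt19 (1.00). The unnumbered ALL library, in another table, held Igf2 at 66.1 and Dlk1 at 64.6 TPM. These 2 rises may therefore reflect low values in the numbered ALL libraries. It held Pigr at 0 and Rnf186 at 1.32 TPM, so those falls are uncertain too, but Ctsz at 136 TPM, near the numbered ALL libraries. Its Muc1, at 141 TPM, and Pdpn, at 8.7, lay between the numbered ALL means and those of ALL-VC. Part of the falls of Muc1 and Pdpn may therefore reflect high values in the numbered ALL libraries.

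For the VC omission, list medians are given relative to the median of all genes, 0.18. AT2 markers had 1 of 20 lower, and 6 lower adjusted over the list alone (-0.77, camera adjusted p = 5.9e-09, adjusted p = 0.65 with an estimated correlation). The interferon list had 1 of 14 lower, and 11 lower adjusted over the list alone (-2.71, camera adjusted p = 1.3e-13, adjusted p = 0.65 with an estimated correlation). As for the MTG omission, these falls may partly reflect high values in the numbered ALL libraries, since the unnumbered one held Isg15 at 0.54 TPM, though Ifit3 at 27.4. Proliferation genes had 0 of 20, then 11 higher adjusted over the list alone (0.88, camera adjusted p = 1.7e-06, adjusted p = 0.70 with an estimated correlation). Basement membrane genes had 0 of 15, then 11 higher adjusted over the list alone (0.59, camera adjusted p = 1.9e-05, adjusted p = 0.65 with an estimated correlation). None was called by fry. The count was 8 and 25 without ALL-VC replicates 1 and 2, 43 and 38 without ALL-FGF10 replicates 1 and 2, 76 without ALL replicate 2, 1309 without ALL replicate 1 (81.8% of them higher, against 26.1%), 51 with only the 2 groups compared (36 of the 119 genes among them) and 27 without a filter on TPM (21 of the 119). All 4 libraries compared held no gene of 100 to 150 nt above 0 TPM.

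**Figure D1:**
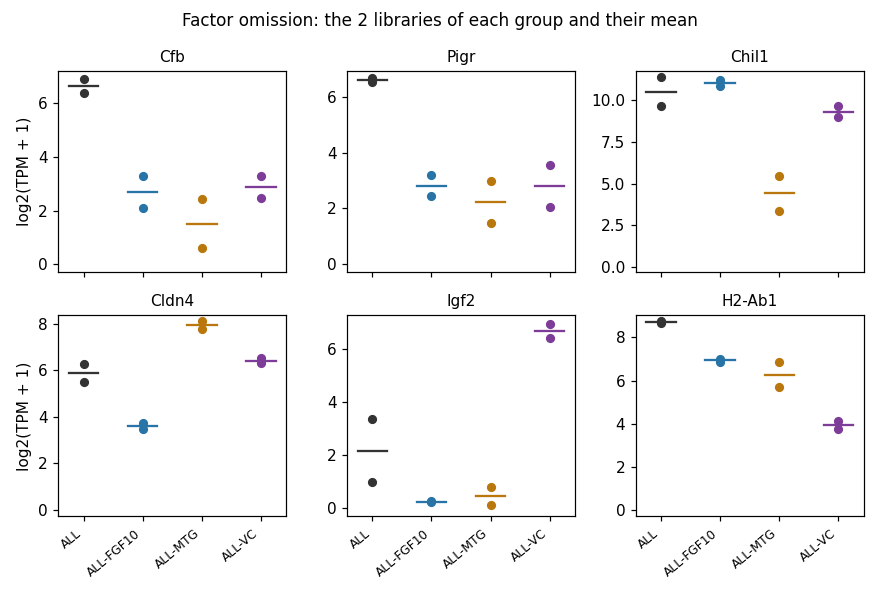
Points are single libraries, 2 per culture group, on a log2(TPM + 1) axis, and bars are group means. Cldn4 had means of 60.1 TPM in ALL, 11.2 in ALL-FGF10, 248 in ALL-MTG and 83.3 in ALL-VC.

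The omissions were next compared with each other, which uses no ALL library as the baseline. Kng2 was higher in ALL-FGF10 than in ALL-MTG (174 ± 2.89 against 1.81 ± 1.04 TPM, n = 2 each, log2 change 6.01, adjusted p = 4.6e-05), as were Chil1 (6.60), the surfactant gene Sftpa1 (1843 ± 140 against 349 ± 82.1 TPM, 2.41), the phosphate transporter gene Slc34a2 of AT2 cells (2.20) and Lyz2 (2.22). Lower in ALL-FGF10 were Cldn4 (11.2 ± 1.67 against 248 ± 43.4 TPM, -4.35, adjusted p = 3.0e-04), the keratin genes Krt8 (-1.85), Krt18 (-1.85) and Krt19 (-1.88), the lipoprotein gene Apoe (-6.67), the intermediate filament gene Vim (-4.06), the WNT targets Lef1 (-2.73) and Tnfrsf19 (-2.40), Ccn2 (-2.54), a YAP target, the coagulation gene F3 (-2.16), Igfbp2 (-2.65), an insulin-like growth factor binding protein gene, and the stress genes Atf3 (-2.57) and Asns (-1.83). Apoe read 1457 and 187 TPM in the ALL-MTG libraries and 4.44 and 3.85 in ALL-FGF10. The total was 521 genes, 264 higher and 257 lower. AT2 markers had 8 of 20 higher, and 13 adjusted over the list alone (median 0.89, fry adjusted p = 0.032, camera adjusted p = 5.5e-07, adjusted p = 0.52 with an estimated correlation). WNT response genes had 2 of 12 lower, and 3 adjusted over the list alone (median -0.78, fry adjusted p = 0.032, camera adjusted p = 3.7e-05, adjusted p = 0.52 with an estimated correlation). Mesenchymal markers had 0 of 5, then 3 lower adjusted over the list alone (median -2.30, camera adjusted p = 0.0025, adjusted p = 0.53 with an estimated correlation). Basal-cell markers had 0 of 6, then 1 lower (fry adjusted p = 0.032, camera adjusted p = 0.010, adjusted p = 0.52 with an estimated correlation), and stress genes 4 of 15 lower, also 4 adjusted over the list alone. The count was 19 and 20 without ALL-FGF10 replicates 1 and 2, 220 without ALL-MTG replicate 1, 285 and 280 without ALL-VC replicates 1 and 2, and 832 and 838 without ALL replicates 1 and 2. Across the 3 libraries that list genes of 100 to 150 nt, 2 of ALL-FGF10 and 1 of ALL-MTG, 2585 genes were called with a spread from the ALL-FGF10 replicates alone.

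ALL-FGF10 and ALL-VC differed in 565 genes, 287 higher and 278 lower (61.3% higher after median-ratio rescaling, 50.8% without). Hc, Muc1 and Ctsz were higher in ALL-FGF10: Hc at 507 ± 46.4 against 73.3 ± 21.6 TPM (n = 2 each, log2 change 2.80, adjusted p = 0.0017), Muc1 by 3.55 and Ctsz by 4.85. The water channel gene Aqp5 of AT1 cells (2.20), Pdpn (2.18) and Slc34a2 (2.08) were also higher. Igf2 (-6.42, adjusted p = 0.0039), Apoe (-4.26), Cldn4 (-2.79), Krt19 (-2.05), the perlecan gene Hspg2 (-1.75) and the glycolysis gene Gapdh (1427 ± 465 to 525 ± 10.0 TPM, -1.40) were lower, and Dlk1 was listed at 0 in both ALL-FGF10 libraries against 18.9 and 8.09 TPM. AT2 markers had 5 of 20 higher, and 7 adjusted over the list alone (camera adjusted p = 2.6e-06, adjusted p = 0.67 with an estimated correlation), and glycolysis and hypoxia genes had 2 of 18 lower, then 8 adjusted over the list alone (camera adjusted p = 3.7e-04, adjusted p = 0.67 with an estimated correlation). The count was 15 and 27 without ALL-FGF10 replicates 2 and 1, 118 and 131 without ALL-VC replicates 1 and 2, 966 and 954 without ALL replicates 1 and 2, and 78 with the listing of 100 to 150 nt genes as a term.

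ALL-MTG and ALL-VC differed in 81 genes, 50 higher and 31 lower (61.7% higher, 71.8% after quantile normalization). Ctsz (119 ± 21.1 against 2.96 ± 2.40 TPM, n = 2 each, log2 change 5.06, adjusted p = 0.0082), the scavenger receptor gene Scara3 (4.58), the glucose transporter gene Slc2a3 (4.52), the calcium-binding gene S100a6 (3.33), Pdpn (2.96) and Tnfrsf19 (2.05) were higher in ALL-MTG. Igf2 (-6.19), Chil1 (-4.90), the resistin-like gene Retnla (-4.40), the calcium channel gene Trpv6 (-3.52) and the club-cell cytochrome gene Cyp2f2 (16.2 ± 4.02 to 1.20 ± 0.0141 TPM, -2.95) were lower, and Dlk1 was listed at 0 in both ALL-MTG libraries. WNT response genes had 1 of 12 higher, and 2 adjusted over the list alone (0.62 above the median of all genes, camera adjusted p = 3.9e-04, adjusted p = 0.78 with an estimated correlation). Mesenchymal markers had 0 of 5, then 2 higher adjusted over the list alone (2.14 above the median of all genes, camera adjusted p = 4.7e-04, adjusted p = 0.78 with an estimated correlation). The count was 6 and 7 without ALL-VC replicates 1 and 2, 16 and 13 without ALL-FGF10 replicates 1 and 2, 33 without ALL-MTG replicate 1, 204 without ALL-MTG replicate 2, 31 with the listing of 100 to 150 nt genes as a term (22 of the 81 genes among them), 18 with only the 2 groups compared (11 of the 81, and 33.3% higher) and 22 without a filter on TPM (13 of the 81).

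How far the 3 omissions moved the same genes was counted next. ALL-MTG and ALL-VC shared 24 genes lower than in ALL and 1 higher, against 0.333 and 0.0419 for independent lists of those sizes. ALL-FGF10 shared 18 lower and 4 higher genes with ALL-MTG (0.533 and 0.176 for independent lists) and 16 lower and 5 higher with ALL-VC (0.838 and 0.272). Cd14, a lipopolysaccharide co-receptor gene, Cd177, Lars2, Pigr and the anion exchanger gene Slc26a4 were lower in all 3, as were the ribosomal RNA-like AY036118 (1109 and 1738 TPM in ALL, 129 to 196 in the other 6 libraries), CT010467.1, Gm16312 and the pseudogene Rpl9-ps4. Cxcl3, Kng2 and the galectin gene Lgals9 were lower in ALL-MTG and ALL-VC, but the unnumbered ALL library held Cxcl3 at 1.35 and Kng2 at 9.78 TPM. In 50 simulations with the same shared ALL libraries and no true difference, the mean number shared was 0.02 for the higher genes of ALL-FGF10 and ALL-MTG and 0 for the other 5 combinations. Changes across 14802 genes correlated at r = 0.404 (ALL-FGF10 with ALL-MTG), 0.373 (ALL-FGF10 with ALL-VC) and 0.516 (ALL-MTG with ALL-VC), against 0.499, 0.50 and 0.494 simulated. The covariances were 0.206, 0.200 and 0.226, against 0.115, 0.116 and 0.114 simulated. The simulations leave out real differences and the independent lists leave out the shared ALL libraries, so the excess over either is no measure of genes moved by every omission. With 2 ALL libraries the controls cannot be split, so part of the excess may come from the shared controls. Among the genes lower in all 3, the unnumbered ALL library held Pigr at 0, Cd177 at 0.06, Lars2 at 56.7 and AY036118 at 325 TPM. It is 1 library from another table. At least for these genes, the shared falls may reflect high values particular to the 2 numbered ALL libraries.

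Arms of the 2C set that add a factor were set beside the omission of the factor of the same name. Across 13618 genes, the difference 2C+VC minus 2C correlated with ALL minus ALL-VC at r = 0.300 (Spearman rho 0.307). For MTG the value was -0.0647 (rho -0.0149). For F10 beside FGF10, names that look alike, it was 0.143 (rho 0.192). The 6 combinations of different names ran from -0.0805 to 0.182. Over the 4 choices of replicate the SD of the VC value was 0.0366. These values describe genes, not independent conditions, and have no p-value.

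How organoids differed from the tips they start from was asked across all ages. Sftpc, encoding surfactant protein C (chromosome 14, 70520949 to 70524081), stood at 81835 ± 19937 TPM in organoids (n = 10) and 119 ± 94.1 in tips (n = 4), a log2 change of 9.81 ± 0.40 SE (adjusted p = 5.5e-11). Slc34a2 (chromosome 5, 53038081 to 53071664) rose from 0.0200 ± 0.0400 to 685 ± 232 TPM (9.31, adjusted p = 4.5e-13). Hmga2, a chromatin gene of early embryos (chromosome 10, 120361275 to 120476469), fell from 415 ± 85.8 to 10.9 ± 4.87 TPM (-5.21, adjusted p = 8.1e-10). The embryonic globin gene Hbb-y (chromosome 7, 103851749 to 103853216) was listed at 0 in all 10 organoids and at 856 to 4637 TPM in tips. In this fit 10392 of 16779 genes were called, 3640 higher and 6752 lower (35.0% higher, 49.1% after median-ratio rescaling and 45.6% after quantile normalization). List medians are therefore given relative to the median of all genes, -0.20.

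All 20 AT2 markers were higher, over all genes and adjusted over the list alone (5.86, fry adjusted p = 3.6e-10, camera adjusted p = 3.2e-15, adjusted p = 0.15 with an estimated correlation). Besides Sftpc and Slc34a2 they included the lysosomal membrane gene Lamp3 (7.80), Chil1 (7.85) and Sftpd, listed at 0 in tips and at a mean of 429 TPM in organoids. Of 20 AT1 markers 17 were higher and 2 lower by either count (2.96, fry adjusted p = 3.4e-08, camera adjusted p = 2.0e-09, adjusted p = 0.30 with an estimated correlation), among them the receptor gene Ager (15.9 ± 4.41 to 635 ± 212 TPM, 5.19), Aqp5 (5.35) and the membrane gene Emp2 (5.97). Club-cell markers had 6 of 11 higher and 1 lower by either count (1.44, fry adjusted p = 4.1e-04, camera adjusted p = 0.037, adjusted p = 0.45 with an estimated correlation). The club-cell carbonyl reductase gene Cbr2 was listed at 0 in tips and at 112 ± 96.5 TPM in organoids. Interferon genes had 7 of 14 higher by either count (1.70, fry adjusted p = 0.024, camera adjusted p = 0.0033, adjusted p = 0.64 with an estimated correlation), such as Ifit3 (3.55) and Psmb8 (3.46). Outside these lists the lysozyme gene Lyz1 was listed at 0 in tips and at 1195 ± 1620.5 TPM in organoids, the nuclear RNA gene Neat1 rose by 7.82, the immediate early gene Egr1 by 4.91 and the junction gene Cldn3 by 1.51 (129 ± 29.4 to 367 ± 50.7 TPM).

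All 20 proliferation genes were lower by either count (-1.96, fry adjusted p = 5.0e-08, camera adjusted p = 3.4e-08, adjusted p = 0.45 with an estimated correlation). The nucleotide reductase gene Rrm2 fell by 2.83 (209.9 ± 23.8 to 29.4 ± 7.13 TPM), the replication genes Mcm2 by 2.55 and Mcm5 by 2.52 and the cyclin gene Ccne1 by 3.13. Distal tip genes had 10 of 14 lower and 3 higher by either count (-1.34, fry adjusted p = 1.2e-06, camera adjusted p = 0.094, adjusted p = 0.64 with an estimated correlation), with Wnt7b at -3.98 (412 ± 31.5 to 27.8 ± 12.1 TPM), the hedgehog ligand gene Shh at -2.82, the RNA-binding gene Lin28b at -3.23, Foxp2 at -1.86 and Etv5, an FGF-responsive factor gene, at -1.06. Hedgehog response genes had 6 of 6 lower by either count (-2.41, fry adjusted p = 3.3e-06, camera adjusted p = 0.026, adjusted p = 0.58 with an estimated correlation), among them the transcription factor gene Gli1 (-2.63). Mesenchymal markers were lower in organoids as well, as given below. Loss of other cells carried by the tips therefore cannot be told apart from a lower hedgehog response in the epithelium. Notch response genes had 7 of 10 lower (-0.74, fry adjusted p = 5.7e-07, camera adjusted p = 0.0497, adjusted p = 0.58 with an estimated correlation), with Notch3 at -3.34 and Nrarp at -2.57. Proximal progenitor genes had 6 of 10 lower and 1 higher (-0.41, fry adjusted p = 5.0e-08, camera adjusted p = 0.35, adjusted p = 0.64 with an estimated correlation), with Sox2 at -3.04 (8.49 ± 2.97 to 0.114 ± 0.190 TPM). Neuroendocrine markers had 5 of 5 lower (-1.01, fry adjusted p = 1.1e-06, camera adjusted p = 0.086, adjusted p = 0.45 with an estimated correlation), among them the ubiquitin hydrolase gene Uchl1 (-4.61). Glycolysis and hypoxia genes had 11 of 20 lower and 1 higher (-1.04, fry adjusted p = 0.020, camera adjusted p = 0.23, adjusted p = 0.86 with an estimated correlation), with the enolase gene Eno1 at -2.97 and the glucose transporter gene Slc2a1 at -2.36.

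Markers of other tissues were lower in organoids as well. Erythroid genes had 9 of 9 lower by either count (-7.47, fry adjusted p = 6.7e-11, camera adjusted p = 3.5e-06, adjusted p = 0.30 with an estimated correlation), and Hba-a1 was listed at 0 in organoids and at 689.5 to 2713 TPM in tips. Mesenchymal markers had 12 of 17 lower, and 13 adjusted over the list alone (-2.0, fry adjusted p = 3.2e-04, camera adjusted p = 0.046, adjusted p = 0.64 with an estimated correlation), among them the collagen gene Col3a1 (-3.89), the elastic fibre gene Mfap4 (-3.65) and, outside the list, the mesenchymal factor gene Foxf1 (-3.99) and the cartilage collagen gene Col2a1 (188 ± 24.9 to 0.210 ± 0.559 TPM, -7.36). Endothelial markers had 9 of 10 lower and 1 higher by either count (-1.19, fry adjusted p = 9.2e-06, camera adjusted p = 0.026, adjusted p = 0.64 with an estimated correlation), such as Cdh5 (-1.99) and Kdr (-1.85). Every tip library held no gene of 100 to 150 nt above 0 TPM and every organoid library 31 to 75. For genes outside the erythroid, mesenchymal and endothelial lists, whether that difference adds to the changes was not tested. Tips held both Xist (45.4 to 90.1 TPM) and Eif2s3y (21.4 to 39.8), whereas organoids held Xist at 192 to 396 with Eif2s3y at 0 to 0.55, except the E9.5 organoid (82.2 and 65.9). With 1 library left out the count was 9563 to 10400.

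**Figure D2:**
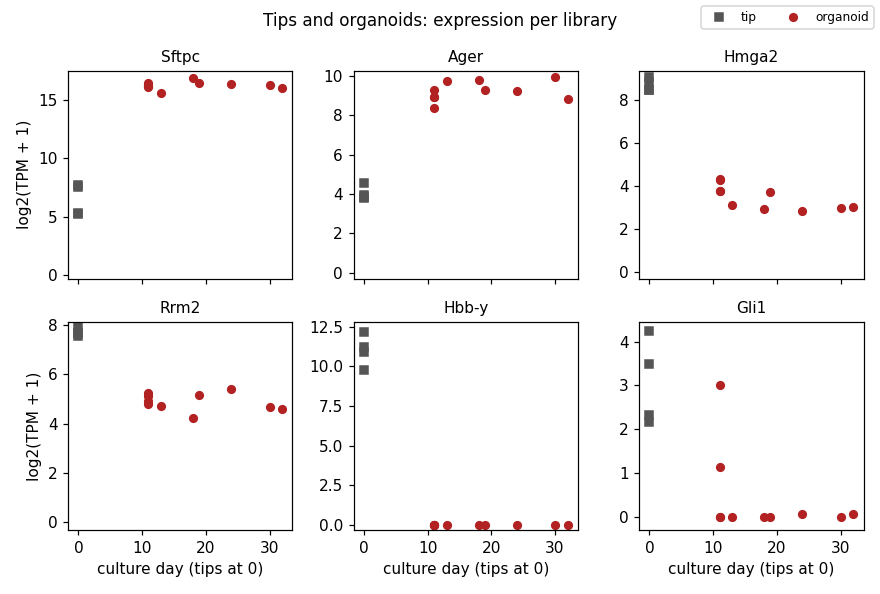
Each point is 1 library on a log2(TPM + 1) axis, with tips as grey squares at day 0 and organoids as red circles against days in culture. Ager averaged 635 TPM in organoids and 15.9 in tips.

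Change with days in culture was tested as a slope across the 10 organoids, adjusted for the stage of the starting tip and given over the 21 days observed. Pigr went from 0.470 ± 0.324 TPM in organoids of 11 to 13 days (n = 5) to 198 ± 34.3 at 30 and 32 days (n = 2), a log2 change of 7.95 ± 0.68 SE (adjusted p = 1.6e-04). Isg15, a ubiquitin-like protein gene induced by interferon (chromosome 4, 156199424 to 156200818), rose from 0.314 ± 0.307 to 29.8 ± 35.3 TPM (4.04, adjusted p = 0.0022). The noncoding gene H19 (chromosome 7, 142575529 to 142578143) fell from 316 ± 336 to 0.130 ± 0.184 TPM (-7.28, adjusted p = 0.0097). The slope was called for 1617 of 16779 genes, 498 higher and 1119 lower (30.8% higher, 59.8% after median-ratio rescaling and 47.8% after quantile normalization). List medians are given relative to the median of all genes, -0.17.

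Interferon genes had 13 of 14 higher, and 14 adjusted over the list alone (3.11, fry adjusted p = 0.0012, camera adjusted p = 2.7e-21, adjusted p = 0.088 with an estimated correlation), among them Oasl2 (3.92), Ifit1 (3.57) and Ifit3 (8.96 ± 7.68 to 74.9 ± 47.7 TPM, 3.45). Isg15 was 54.7 TPM at day 30, 4.79 at day 32 and 20.1 at day 24. Glycolysis and hypoxia genes had 16 of 20 higher, and 18 adjusted over the list alone (1.59, fry adjusted p = 0.0012, camera adjusted p = 4.2e-23, adjusted p = 0.088 with an estimated correlation), such as Pgk1 (107 ± 9.79 to 545 ± 91.8 TPM, 2.36), the hypoxia gene Ndrg1 (3.51) and Egln3, an oxygen sensor gene (3.03). AT2 markers had 3 of 20 higher and 2 lower, then 4 and 2 adjusted over the list alone (0.74, camera adjusted p = 0.0026, adjusted p = 0.53 with an estimated correlation). Among them, Sftpd rose (4.87) and Hc fell (331 ± 93.1 to 72.0 ± 40.8 TPM, -2.49). AT1 markers had 1 of 20 higher by either count, Rtkn2 (2.49). Other rises were Lyz1 (5.41), the iron-binding gene Lcn2 (5.87), the platelet factor gene Pf4 (6.25) and the secreted gene Sectm1b (5.30).

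Distal tip genes had 5 of 14 lower with culture day, and 6 adjusted over the list alone (-0.50, fry adjusted p = 4.2e-04, camera adjusted p = 0.0079, adjusted p = 0.088 with an estimated correlation). They included Shh (38.5 ± 17.6 to 8.49 ± 4.62 TPM, -2.10), Sox9 (-0.99) and Foxp2 (-1.23). BMP response genes had 5 of 12 lower, and 6 adjusted over the list alone (-0.49, fry adjusted p = 0.0030, camera adjusted p = 0.0017, adjusted p = 0.39 with an estimated correlation), with Id1 at -1.65 and Atoh8 at -1.50. Basement membrane genes had 7 of 16 lower, then 8 lower and 1 higher adjusted over the list alone (-0.70, fry adjusted p = 0.0030, camera adjusted p = 0.0016, adjusted p = 0.39 with an estimated correlation), with the laminin gene Lamb1 at -2.43 and the matrix gene Fras1 at -2.19. The imprinted genes Igf2 (-5.24), Dlk1 (-6.31) and Meg3 (-5.83), the cadherin gene Cdh16 (126 ± 25.3 to 2.02 ± 0.361 TPM, -5.85) and Mcm2 (-0.98) fell. The count was 430 without the E10.5 organoid of day 32 and up to 1825 without another library. With start stage as a block, in the E10.5, E13.5 and E14 organoids only, 161 genes were called.

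**Figure D3:**
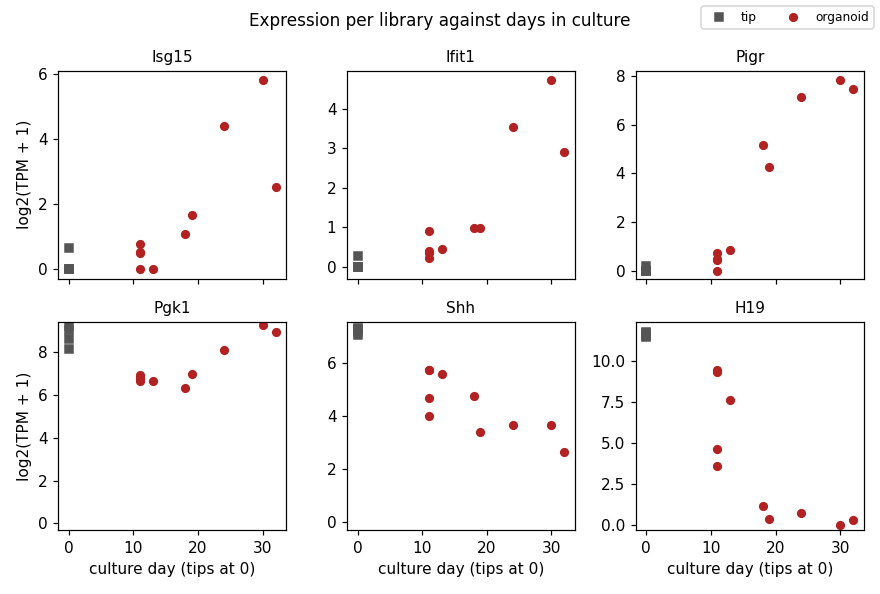
Each point is 1 library on a log2(TPM + 1) axis, tips as grey squares at day 0 and organoids as red circles against days in culture. Pgk1 averaged 107 TPM at 11 to 13 days and 545 at 30 and 32 days.

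The stage of the starting tip was tested as a second slope across the organoids, over the 4.5 days observed. Few genes followed it. The mitochondrial ribosome gene Mrps10 (chromosome 17, 47368887 to 47381417) was 14.7 ± 4.00 TPM in organoids of 11 to 13 days from E9.5 to E11.5 tips (n = 3) and 34.8 ± 13.4 in 11-day organoids from E13.5 and E14 tips (n = 2), a log2 change of 1.68 ± 0.21 SE (adjusted p = 0.013). St8sia6, a sialyltransferase gene (1.62), the calcineurin regulator gene Rcan2 (1.62) and the methionine reductase gene Msrb3 (1.25) also rose, and in all 9 genes were called, 7 higher and 2 lower. Club-cell markers had 0 of 11 called by either count, yet moved lower as a set (median -0.66, fry adjusted p = 0.0071, camera adjusted p = 0.0038, adjusted p = 0.15 with an estimated correlation). The count was 2 without the E14 organoid of day 11, and 5 without the E12.5 tip, the E13.5 tip, the E10.5 organoid of day 11 or the E14 organoid of day 24. No other library moved it beyond 10. In organoids of 11 to 13 days alone 4 genes were called, all lower, with 1 of the 9 among them. Mrps10 and the other rises were thus not called there.

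Among the tips themselves, embryonic day was tested as a slope over the 3 days observed, with the spread of all 14 libraries. Lin28a, an RNA-binding gene of early embryos (chromosome 4, 134003330 to 134018841), fell from 25.1 TPM at E10.5 to 0.0900 at E13.5 (n = 1 each, log2 change -4.84 ± 0.41 SE, adjusted p = 4.3e-04). The aldehyde dehydrogenase gene Aldh1a7 (chromosome 19, 20692953 to 20727562) rose from 1.89 to 68.4 TPM (5.07, adjusted p = 0.0048). Of 123 called genes, 34 were higher and 89 lower. Higher with stage were the glutathione peroxidase gene Gpx2 (3.81), the cholecystokinin receptor gene Cckar (3.70), the chloride channel gene Cftr (3.37), the factor gene Nfix (3.14), Sftpc (37.0 to 210.4 TPM, 2.90) and the laminin gene Lamb3 (2.45). Lower were Lin28b (-2.32), the homeobox gene Nkx2-6 (-4.54), the transthyretin gene Ttr (-4.14), the lactate dehydrogenase gene Ldha (-1.35), the embryonic globin gene Hbb-bh1 (-4.77) and the peptide gene Pyy, listed at 0 at E13.5 and 24.3 TPM at E10.5. BMP response genes had 0 of 12 called, and 5 lower adjusted over the list alone (median -1.03, fry adjusted p = 0.017, camera adjusted p = 7.8e-07, adjusted p = 0.17 with an estimated correlation). The count was 14 without the E13.5 tip, 77 without the E11.5 tip, 62 to 77 without any 1 of the 9 organoids other than that from E9.5, and 0 in the 4 tips alone. A pseudocount of 0.1 gave 25 calls, most of them higher, with 19 of the 123 among them. A filter of 5 TPM gave 42, and no filter gave 335. Values of single tips carry no replicate.

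Whether position or size set the cut pieces apart was tested in 9 libraries, with terms for up against down, left against right and piece size. No gene was called in any of the 4 contrasts by limma over 15017 genes. Without the filter on TPM this did not hold for cut pieces against the intact organoid, a group of 1 library. Up against down had 663 genes at unadjusted p under 0.05, left against right 463, the 4 smaller pieces against the 4 larger pieces 799 and cut pieces against the intact organoid 681. The smallest adjusted p-values were 1, 1, 0.533 and 0.332. Of the 4 genes with the smallest p per contrast, which did not pass, the antizyme inhibitor gene Azin1 (chromosome 15, 38487427 to 38519266) was 36.2 ± 1.96 TPM in up pieces and 70.3 ± 8.53 in down pieces (n = 3 each). Others in that contrast were Cbarp, a calcium channel regulator gene (10.6 ± 1.64 and 28.5 ± 8.95 TPM), and the metallothionein gene Mt1 (175 ± 26.3 and 94.0 ± 21.2). Between left and right, Cckar was 6.81 ± 4.44 and 20.8 ± 2.98 TPM, the chitinase gene Chia1 4.45 ± 0.672 and 11.4 ± 1.69, the muscle LIM gene Csrp2 22.5 ± 5.61 and 41.6 ± 1.17 and the G-protein regulator gene Rgs4 90.4 ± 39.1 and 30.0 ± 9.99.

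By size, the ion transport regulator gene Fxyd3 was 3.11 ± 1.58 TPM in the smaller pieces and 20.5 ± 7.73 in the larger pieces (n = 4 each), Pf4 205 ± 36.6 and 102 ± 24.1, the zinc finger gene Zfp647 2.03 ± 0.537 and 7.13 ± 1.12 and the antimicrobial gene Pglyrp1 122 ± 40.5 and 46.2 ± 9.95. Against the intact organoid (n = 1), Sgk1 was 41 ± 9.00 TPM in the 8 pieces and 10.3 intact, the phosphatase gene Phospho1 33.4 ± 11.9 and 8.60, the receptor gene Gprc5b 5.83 ± 1.93 and 0.260 and the linker gene Clip4 48.5 ± 16.5 and 13.7. In cut against intact the list medians were 0.50 for AT1 markers, -0.85 for proliferation genes, 1.21 for mesenchymal markers and 0.40 for steroid and cAMP response genes. With 1 intact library, these differences cannot be told from the spread of single libraries. In left against right, interferon genes had a median of -1.29 (camera adjusted p = 3.9e-08, adjusted p = 0.86 with an estimated correlation). No list passed fry in any of the 4 contrasts. Leaving out up-half-left (5) gave 4 calls for cut against intact and leaving out down-half (2) gave 1, leaving out right-half (4) gave 6 for piece size and 1 for left against right, leaving out down-half-right (8) gave 1 each for up against down, left against right and size, and leaving out down-half (2) gave 1 for size. Xist was 216 TPM in the intact organoid and 212 in up-half-left (5), both with Eif2s3y at 0. In the other 7 pieces Xist was 0.02 to 5.4 TPM and Eif2s3y 65.2 to 92.8. Pieces cut from 1 organoid of 1 sex would not be expected to differ in this way. Cutting therefore cannot be told apart from the difference in sex-linked genes for those 7 pieces, which are all that remain without up-half-left (5).

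The LO libraries, at days 8, 11 and 18, were compared as single libraries, so no p-value or replicate check applies to them or to the 2C set. A gene counted when at least 2-fold apart on the log2(TPM + 1) scale with 5 TPM or more in the higher library. Sftpc read 12436, 36975 and 109318 TPM at days 8, 11 and 18. Sftpb, another surfactant gene, read 239.6, 970 and 7141 TPM, and Chil1 1.17, 2.51 and 2071. From day 8 to day 11, 592 genes differed, 268 higher and 324 lower (median of all genes -0.10), with 10 of 18 AT2 markers higher (median log2 difference 1.10), among them the protease gene Napsa (1.02 to 17.0 TPM) and Hc (50.5 to 143). Of 10 mesenchymal markers 4 were higher and 1 lower, with Col3a1 at 0.48 and 12.9 TPM. From day 8 to day 18, 2292 genes differed, 857 higher and 1435 lower (median of all genes -0.26). All 20 AT2 markers were higher (5.09), such as Sftpd (1.07 to 1024 TPM), Slc34a2 (1.38 to 1135), Lamp3 (1.35 to 687) and Sftpa1 (12.7 to 982). Of 20 AT1 markers 13 were higher (1.27), with Aqp5 at 2.94 and 80.3 TPM and Rtkn2 at 7.71 and 43.3. Also higher were Lcn2 (0.81 to 1271), Lyz1 (0.54 to 1253), the chemokine gene Cxcl5 (0.56 to 786) and Cbr2 (0.81 to 124). Of 20 proliferation genes 19 were lower (-1.32), such as Mki67 (54.5 to 22.5 TPM) and Top2a (127 to 53.2), and of 13 WNT response genes 8 were lower and 1 higher (-1.04), such as Lef1 (6.91 to 1.91) and the stem-cell receptor gene Lgr5 (6.31 to 1.91). The laminin gene Lama1 read 17.1 and 0.30 TPM, Hmga2 31.3 and 6.92 and Igf2 1380 and 1.60. From day 11 to day 18, 1585 genes differed (711 higher, 874 lower, median of all genes -0.14), with 20 AT2 markers and 8 AT1 markers higher, 12 proliferation genes and 4 of 10 mesenchymal markers lower, and Col3a1 at 12.9 and then 0 TPM.

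With DCI at day 11, 2748 genes differed from the day 11 library without it, 1270 higher and 1478 lower (median of all genes -0.08). Of 20 AT1 markers 18 were higher (median log2 difference 2.54), such as Ager (427 to 3508 TPM), Aqp5 (5.45 to 403), the homeobox gene Hopx (112 to 949) and the chloride channel gene Clic5 (1.02 to 65.5). AT2 markers had 16 of 20 higher (3.47), such as Sftpd (1.89 to 737), Slc34a2 (17.6 to 1336) and Sftpa1 (28.5 to 942). Club-cell markers had 6 of 11 higher and 1 lower, with the secretoglobin gene Scgb1a1 at 413 TPM against 0. Mesenchymal markers had 2 of 14 higher and 1 lower (0.36), with Pdgfra at 0.03 and 14.7 TPM, Tbx4 at 0.20 and 5.61 and Dcn at 34.4 and 0.66. Of 18 steroid and cAMP response genes 13 were higher (1.68), such as Fkbp5 (6.69 to 92.8), Tsc22d3 (26.8 to 114), Per1 (17.1 to 59.2) and Zbtb16 (0.04 to 20.9). All 20 proliferation genes were lower (-2.26), with Mki67 at 42.6 and 3.86 TPM and Top2a at 96.7 and 11.1. BMP response genes had 9 of 11 lower (-2.08), such as Id1 (273 to 63.2), Id2 (624 to 119.8) and Id3 (189 to 25.3), and distal tip genes 9 of 12 (-1.24), such as Sox9 (64.8 to 19.2) and Wnt7b (74.7 to 4.89). Bmp4 read 411 and 109 TPM. The largest rises beyond these lists included Tmem213 (0.42 to 297), a membrane protein gene, and the proton pump gene Atp6v0a4 (0.18 to 121).

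The last comparisons set 3 additions beside the 2C library. With F10, 643 genes differed, 336 higher and 307 lower (median of all genes 0.02). AT2 markers had 10 of 20 higher (median log2 difference 0.87), such as Sftpd (28.5 to 182 TPM) and Lyz2 (15.1 to 86.6). Club-cell markers had 5 of 11 (1.19), with Scgb1a1 at 19.0 and 371 TPM, Cyp2f2 at 115 and 326 and Scgb3a2 at 10.4 and 49.0. Ciliated-cell markers had 4 of 17 higher (0.85), such as the dynein gene Dynlrb2 (15.6 to 52.2). Mesenchymal markers had 6 of 12 higher (1.88), such as Col3a1 (0.54 to 54.4), Col1a1 (0.87 to 26.4) and Mfap4 (0.50 to 17.2), and outside the list the proteoglycan gene Bgn read 0.75 and 48.3. FGF response genes had 0 of 10, with Etv5 at 158 and 99.8 TPM, and proliferation genes 6 of 20 lower. With MTG, 812 genes differed, 280 higher and 532 lower (median of all genes -0.13). Club-cell markers had 8 of 11 lower (-2.50), with Cyp2f2 at 115 and 3.24 TPM and Scgb1a1 at 19.0 and 0.53, and ciliated-cell markers 6 of 13 (-2.16), with Foxj1, a ciliogenesis factor gene, at 10.1 TPM and then 0. AT2 markers had 8 of 20 lower and 1 higher (-0.25), with Muc1 at 272 and 18.5 TPM, Hc at 283 and 56.4 and Sftpb higher, at 1430.2 and 3618. The haptoglobin gene Hp read 79.7 and 1.20. Distal tip genes had 4 of 12 higher (0.58), such as Bmp4 (44.9 to 228) and Etv4 (2.69 to 15.2), whereas WNT response genes had 0 higher and 1 lower, with Axin2 at 11.4 and 12.2. With VC, 1062 genes differed, 642 higher and 420 lower (median of all genes -0.10). AT2 markers had 18 of 20 higher (1.72) and AT1 markers 13 of 20 (1.16), such as Sftpa1 (74.0 to 902), Slc34a2 (327 to 1470), Aqp5 (13.6 to 170) and Ager (735 to 1685). Scgb1a1 read 4156 TPM against 19.0, Chil1 416 against 3.46, the cilium gene Tppp3 121 against 42.0 and the FGF response gene Dusp6 31.1 against 11.6. Xist was 446 TPM in 2C and 0.21 and 0.30 with MTG and VC, where Eif2s3y was 83.3 and 85.1 against 0. The ALL library without a replicate number, compared with 2C after the values were seen, differed in 1346 genes, 534 higher and 812 lower (median of all genes -0.24), with Cyp2f2 at 0.98 TPM against 115 and Bmp4 at 241 against 44.9.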

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

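The tests of the length listing, of short or predicted genes, of leukocyte markers and of the groupings of pieces were chosen after the results were seen, including the bounds for short genes and the use of the leukocyte list. The tests of rescaling, of the order of culture days, of the pieces as a reference and of the grouping of organoids and tips were chosen before their values were computed.

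The 271 genes called between ALL-FGF10 and ALL are the first pattern. ALL-FGF10 libraries list genes of 100 to 150 nt and ALL libraries do not, so a difference in library making or read handling could contribute. With that listing as a term, the median change of the genes called higher kept 94.7% of its size and that of the genes called lower 101.3%, but only 1 group holds both kinds, so the test has little power. Genes under 300 nt or with predicted names made up 46.9% of the called genes against 19.4% of all genes tested, which may mean that part of the count reflects them. Neither explanation is settled by these values.

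The rise of interferon genes with culture day is the second. Leukocytes among the cells are an unlikely source, because the leukocyte markers had a median of 0.010 TPM at 30 and 32 days and 1 was called higher, Lcp1 (27.9 to 136 TPM in organoids). A shift in the TPM share of abundant transcripts is also unlikely, since 14 of 14 interferon genes were called after median-ratio rescaling against 13 without. Of 100 orders of the culture days, 1, the real one, gave as many, and the highest other order gave 2. Total calls were 1617 for the real order and 499 for the highest other.

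The lower level of blood, endothelial and mesenchymal markers in organoids than in tips is the third. Pieces and the intact organoid, whose libraries, as those of the tips, have no gene of 100 to 150 nt above 0 TPM, held 30 called markers at a median of -2.73 relative to tips in log2(TPM + 1), so the listing alone is an unlikely cause, although tables were normalized separately. Other cells collected with the tips are a candidate explanation that these values do not settle. Of 8 measured leukocyte markers, a list outside the pattern, 5 (62.5%) were called lower and 1 higher. Over all genes, 6752 of 16779 were called lower, so a large share was lower in any case. For the leukocyte list, camera with the preset correlation gave adjusted p = 0.28 and fry gave adjusted p = 1.7e-04. The shares called lower were 100% for erythroid, 90% for endothelial and 70.6% for mesenchymal markers. The labels do not mention a sort that would remove such cells.

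For organoids against tips, 1 of 100 groupings, the real one, reached 10392 calls, and the highest other reached 3721. For pieces, the real groupings gave 0 calls, which every grouping reaches, so these tests can decide nothing. By size, 35 of 35 groupings did so, and the highest other gave 5. For up against down and for left against right, all 10 groupings did so, and the highest others gave 7 and 5.

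Of 320 sets of values tested for a library that stands apart from the others of its kind, 33 had one, and some would by chance. All values are log2(TPM + 1) with the range of the other libraries in brackets where it is informative. Among tips, E10.5 stood apart in Chil1 (0.70) and Slc34a2 (0.11), E11.5 in Cdh5 (2.98, others 1.51 to 1.75), Sox2 (2.34, others 3.41 to 3.49) and Pigr (0.23), E12.5 in Aqp5 (0.92, others 0), Ifit1 (0.29), Isg15 (0.65) and Neat1 (0.74), and E13.5 in Cldn3 (7.44, others 6.82 to 6.91), Hbb-bh1 (5.15, others 9.92 to 10.41), Psmb8 (0.96) and the mean of the gut and gastric list (0.22). Among organoids, E10.5 day 11 stood apart in Gli1 (3.02, others 0 to 1.13), E11.5 day 11 in Foxf1 (3.11, others 0 to 0.53), Col2a1 (1.48) and Kdr (0.29), E13.5 day 11 in Chil1 (3.24, others 7.02 to 11.08) and Lin28a (0.070), E9.5 day 13 in Emp2 (8.78, others 7.61 to 8.17), Lin28b (0.12) and Sox2 (0.69), E10.5 day 18 in the proliferation mean (4.50, others 5.06 to 5.64) and E13.5 day 30 in Cdh5 (0.084). Among pieces, up-half (1) stood apart in the means of the lung epithelium (6.80, others 7.11 to 7.17), AT1 (6.73, others 7.26 to 7.31) and stress lists (4.29, others 5.03 to 5.18) and in Tmsb15b2 (2.12, others 0). Right-half (4) did so in Fxyd3 (3.34), up-half-right (6) in the distal tip mean (3.83), down-half-left (7) in the erythroid mean (0.15) and down-half-right (8) in the basement membrane mean (5.66, others 5.06 to 5.16) and Clip4 (5.71, others 4.87 to 4.99).

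For 66 genes the slope on embryonic day differed between tips and organoids by limma, among them Nkx2-6 (tip minus organoid -1.51 ± 0.13 SE log2 per day, adjusted p = 0.0010), Lin28a (-1.62, adjusted p = 0.0011), Cobl (0.76), Lamb3 (0.75), Rfx6 (-1.18) and Aldh1a7 (1.80). Lin28a was at 0 in every organoid except that of E13.5 day 11 (0.070 log2(TPM + 1)). For a gene absent from organoids, the difference only restates the tip slope.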

How the results depend on the processing

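The alternatives with a term or a choice of libraries for genes of 100 to 150 nt, with genes of at least 300 nt, with the organoids alone for the culture day slope and with the unnumbered ALL library against 2C were chosen after the results were seen, and the others before the data were examined. The limits are small groups, TPM without counts and unknown origin of replicates. Of 340 alternatives for these results, 230 were labelled as within 1.5 times and 110 as moved further, and the cause of each move was not tested. A count has no sign, so a turn in direction shows only in the share of called genes that were higher. That share was 30.8% for the culture day slope, against 59.8% with median-ratio rescaling and 60.2% with start stage as a block, and 27.6% for the tip stage slope, against 68% with a pseudocount of 0.1. Without ALL replicate 1 it was 76.3% in place of 48.0% for ALL-FGF10 against ALL, 50.8% in place of 26.3% for ALL-MTG against ALL and 81.8% in place of 26.1% for ALL-VC against ALL. With only the 2 groups compared it was 33.3% in place of 61.7% for ALL-MTG against ALL-VC, and without a filter on TPM 69.3% for ALL-FGF10 against ALL. For the start stage slope it was 77.8% of 9 genes and 0 of 4 in organoids of 11 to 13 days. Not every such turn is listed here. A setting chosen beforehand that adds the unnumbered ALL library to the ALL group was not applicable, because that library stands in another table.

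A pseudocount of 0.1 gave 177 calls in place of 271 for ALL-FGF10 against ALL and 25 in place of 123 for the tip stage slope. Without a filter on TPM the counts were 7 for ALL-MTG against ALL (76), 27 for ALL-VC against ALL (119), 22 for ALL-MTG against ALL-VC (81), 3 for the start stage slope (9), 335 for the tip stage slope and 184 for pieces against the intact organoid (0). A filter of 5 TPM gave 42 for the tip stage slope, and the 4 tips alone gave 0. For ALL-VC against ALL, median-ratio rescaling gave 190, quantile normalization 189 and robust estimation 188, and robust estimation gave 115 for ALL-MTG against ALL.

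With only the 2 groups compared, the counts were 166 for ALL-FGF10 against ALL, 11 for ALL-MTG against ALL, 51 for ALL-VC against ALL, 2158 for ALL-FGF10 against ALL-VC (565) and 18 for ALL-MTG against ALL-VC. With the replicate block the counts were 143, 48 and 68 for ALL-FGF10, ALL-MTG and ALL-VC against ALL and 45 for ALL-MTG against ALL-VC, but the pairing of replicate numbers is not explained by the labels, and correlations of deviations from the group mean between equal numbers ran from -0.07 to 0.114. The term for genes of 100 to 150 nt gave 68, 24, 78 and 31 for ALL-FGF10 against ALL, ALL-MTG against ALL, ALL-FGF10 against ALL-VC and ALL-MTG against ALL-VC, and 32 of the 271 genes were still called. Libraries without such genes gave 20, 53 and 5 for ALL-MTG against ALL, ALL-VC against ALL and ALL-MTG against ALL-VC, each with 1 or 2 libraries per group, and libraries with them 2585 for ALL-FGF10 against ALL-MTG (521), with 1 ALL-MTG library. Start stage as a block gave 161 for the culture day slope (1617), 158 of them among the genes called without it, and organoids of 11 to 13 days gave 4 for the start stage slope.

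With 1 library left out, counts ran from 9 to 1149 (ALL-FGF10 against ALL), 18 to 191 (ALL-MTG against ALL), 8 to 1309 (ALL-VC against ALL), 19 to 838 (ALL-FGF10 against ALL-MTG), 15 to 966 (ALL-FGF10 against ALL-VC), 6 to 204 (ALL-MTG against ALL-VC), 9563 to 10400 (organoids against tips), 430 to 1825 (culture day), 2 to 10 (start stage) and 14 to 120 (tip stage). For pieces they ran from 0 to 1 (up against down and left against right), 0 to 6 (size) and 0 to 4 (against intact).

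For single libraries, a minimum of 1 TPM in place of 5 gave 1428 for LO day 11 against day 8 (592), 3629 for day 18 against day 8 (2292), 2715 for day 18 against day 11 (1585), 4163 for DCI (2748), 1480 for F10 (643), 1714 for MTG (812), 2030 for VC (1062) and 2426 for the unnumbered ALL library (1346). A minimum of 10 TPM gave 392 for LO day 11 against day 8 and 419 for F10, and genes of at least 300 nt gave 425 for F10. Of list tests over all contrasts, camera with the preset correlation called 97, camera with an estimated correlation 0 and fry 35. The VC correlation across tables was 0.344 with TPM of at least 5 and 0.213 with a pseudocount of 0.1, against 0.300.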

Other observations

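The lists of imprinted, MHC class II, ribosomal RNA-like and sex-linked genes were chosen after their values were seen, as were Cd74, Grb10 and AY036118 as genes to name.

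Imprinted genes of the fetal growth network were lower in organoids than in tips, 16 of 16 called by either count. The slope on culture day was also negative for 11 of 16, and for 12 adjusted over the list alone. Igf2 was 1282 to 1554 TPM in tips, 262 in the E10.5 organoid of day 11 and 0.38 in that of day 32. Without VC, 3 of 15 genes were called higher than in ALL, Igf2, Dlk1 and Grb10 (log2 change 1.30, adjusted p = 0.037), and 6 were higher and 1 lower adjusted over the list alone. The unnumbered ALL library held Igf2 at 66.1 and Dlk1 at 64.6 TPM, so their rises may reflect low values in the numbered ALL libraries. Without FGF10 or MTG 0 were called by either count, and ALL-MTG had 2 of 15 lower than ALL-VC. The difference between omissions was not tested for the list. In the LO libraries 12 of 16 were lower at day 18 than at day 8, with Meg3 at 1.06 and 196 TPM. H19 was 1616 TPM in 2C, 1248 with MTG, 299.6 with F10, 25.1 with VC and 80.6 in the ALL library without a replicate number, while Meg3 was 90.1 TPM in 2C and 112 with VC.

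MHC class II genes were higher in organoids than in tips, 7 of 7 called by either count, and Cd74 had a log2 change of 7.30 (adjusted p = 6.2e-06). They rose with culture day in 4 of 7, and in 7 adjusted over the list alone. They were lower than in ALL without VC (4 of 7, then 7 adjusted over the list alone), without MTG (3, then 6) and without FGF10 (1, then 5). Cd74 was 2302 and 2600 TPM in the numbered ALL libraries, 234 and 369 in ALL-VC and 586 in the unnumbered ALL library. With DCI at day 11, 7 of 7 were lower, and H2-Aa was 3.51 TPM against 212.

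Sex-linked genes differed between libraries of the same group. ALL replicate 1 held Eif2s3y at 74.5 TPM and Xist at 6.04, and replicate 2 held 0.22 and 147. In the 2C set, Xist was 446 TPM in 2C, 277 with F10, 212 in the unnumbered ALL library, and 0.21 and 0.30 with MTG and VC. LO day 8 held Xist at 332 and Eif2s3y at 43.2 TPM, and the LO libraries of days 11 and 18 held Eif2s3y at 0.11 and 0.

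In the omission table and among tips, Lars2 and AY036118, a ribosomal RNA-like transcript, were highest in the same libraries. AY036118 was 1109 and 1738 TPM in ALL against 129 to 196 in the other 6 culture libraries, and Lars2 was 307 and 480 against 17.5 to 51.1. The E11.5 tip held 1226 and 1538 TPM, against 40.6 to 116 and 65.8 to 99.1 in the other tips. Of 16 other mitochondrial tRNA synthetase genes, none was called in any omission against ALL. The falls of Lars2 called in each omission therefore cannot be told apart from the high AY036118 of the numbered ALL libraries. In the 2C set AY036118 was highest in the unnumbered ALL library (325 TPM) and Lars2 with VC (83.0 TPM).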
